A study of Homo sapiens with 26 samples.

How the data were processed

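tRNA sequencing libraries of HEK293T cells were grouped by their GEO titles into 13 groups of 2 replicates. The GEO descriptions of the R-TCT-4, W-CCA-2 and W-CCA-4 libraries name R-TCT-1 instead, and the titles were used. Each of 14 deposited count files, 1 per library, listed tRNA names that all ended in copy number 1, and 6 whole-series tables held the other 12 libraries, with isoacceptor and isodecoder values for each of 3 stop codons. The number of columns with no sample was 0. Columns of the whole-series tables are named by stop codon, a code and a replicate number. The code 3 was assigned to RESTART v3 and the code 1 to gctrl by elimination, which no label states. Names were matched to RefSeq GRCh38.p14 symbols for 241 tRNAs, and overlapping genes were taken from GENCODE v29. Mitochondrial tRNA names numbered 0.

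The counts were deposited by the authors as raw counts per tRNA name, and their processing notes list Trim Galore (no version), UMI-tools 1.0.0, BWA 0.7.17-r1188, HTSeq 1.14 and GRCh38 without giving the order or role of each. How reads that fit several tRNAs were counted is not described. The values deposited beside the counts as RPKM are reads per 1000000 (RPM), which the authors made by dividing each count by 1 number per library, with no length term. The signal values were deposited by the authors as normalized expression per isoacceptor or isodecoder. Their column totals run from 732359 to 1121706, so a further normalization that is not described was applied. The plan had assumed TPM and RPKM, and the values turned out to be signal and RPM.

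Count totals over the listed tRNAs were 12466839 to 12798174 in 13 libraries and 1866933 in the R-TCT-4 library of replicate 2. The floor of 3 counts lay at 0.234 to 0.241 CPM in the former and 1.61 CPM in the latter. The 10 most abundant tRNAs took 36.6% to 38.8% of counts, and 45.8% in the R-TCT-1 library of replicate 2. Between replicates chi-square per degree of freedom was 241 to 7541, so spread between libraries exceeded counting error and set the precision. No whole-number step was found in the signal values, so counts and depth could not be recovered from them.

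Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, 1 fit over all 14 libraries with a coefficient per group, and the quasi-likelihood F test of each overexpression group against untreated cells over 252 tRNAs. Log2 CPM used a prior count of 2. Signal values were analysed with limma 3.58.1 on log2(signal + 1) for features with a mean of at least 10. The empirical Bayes step used a trend for isodecoders and none for isoacceptors. RESTART v3 was compared with gctrl in the 4 libraries of each stop codon, and over the 12 libraries with stop codon as a covariate. The difference of the effect between stop codons was tested as an interaction over the 12 libraries. Adjusted p-values are Benjamini-Hochberg values over all features of a test, and a feature was called at an adjusted p under 0.05. Means are over 2 libraries with their SD.

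Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Fry's first p-value tests whether a list moves one way on balance, and its mixed p-value tests change in either direction. The near-cognate lists were Gln-TTG, Glu-TTC, Lys-TTT, Ser-TGA, Leu-TAA and Tyr-GTA for UAA, then Gln-CTG, Glu-CTC, Lys-CTT, Ser-CGA, Leu-CAA, Trp-CCA and Tyr-GTA for UAG, and Arg-TCG, Arg-TCT, Gly-TCC, Ser-TGA, Leu-TAA, Cys-GCA and Trp-CCA for UGA. The comparisons, lists, tests, the rule for naming tRNAs and 124 alternatives were chosen before the data were examined, and 10 alternatives were added afterwards.

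The rule named each overexpressed tRNA, the isodecoders of its anticodon, and up to 10 highest and 10 lowest called tRNAs with both libraries on the same side of both untreated libraries. In the signal tables it named the near-cognate isoacceptors, SeC-TCA, up to 10 highest and 10 lowest called features with non-overlapping groups and, with fewer than 5 called, the 3 highest and 3 lowest non-overlapping features with a mean signal of at least 100. Leu-TAA-4-1, the anticodons of the R-TCT-1 library of replicate 2, and Asp-GTC-2 and Gly-GCC-1 were named after their values had been seen. The SD of log2 fold changes that replicate differences alone would give was the root of the summed squares of the SDs of the replicate differences of both groups over 4.

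Alternatives for counts were RLE and library-size scaling, scaling without the 6 targets, no filter or a mean count of at least 50, a replicate block, a robust fit, other reference groups, only the 2 groups compared, DESeq2 1.42.0, limma on log2(RPM + 1), and leaving out single libraries. For signal values they were pseudocounts of 10 and 0.1, no filter or a mean of at least 100, median centring, quantile normalization, the other trend setting, replicate and crossed blocks, all 12 libraries in one fit, an average over 6 groups, and leaving out single libraries. Where an alternative gave a sample variance of 0, limma offset it from 0.

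The models were tested on simulated data with changes of 2-fold and 4-fold in 40 tRNAs or 8 isoacceptors. This was run after the first analysis of the real data. In counts 50% to 85% of 2-fold and 95% to 100% of 4-fold changes were recovered, with 1 to 3 false calls. With 2 against 2 signal libraries the shares were 5% to 75% and 60% to 100% of isodecoders with 0 to 4 false calls, and 0% to 75% and 25% to 100% of isoacceptors with 0 false calls. The lowest shares were in the TAA tables. The interaction test recovered 15% and 70% of isodecoders and 25% and 50% of isoacceptors, and the fit over 12 libraries 90% and 95% of isodecoders and 100% of isoacceptors. All these shares rest on many changes at once, which ease the Benjamini-Hochberg cut, and on features drawn independently. They may overstate recovery where few tRNAs change or tRNAs move together. In the real counts the overexpressed tRNAs with folds of 1.75 to 2.14 were not called. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Reads were not used here.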

Results

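tRNA levels were measured by sequencing in HEK293T, a human embryonic kidney cell line, in 26 libraries from 13 groups of 2 replicates. Deposited count files covered 7 groups, untreated cells and cells overexpressing 1 of 6 tRNAs, Arg-TCG-1-1, Arg-TCG-4-1, Arg-TCT-1-1, Arg-TCT-4-1, Trp-CCA-2-1 or Trp-CCA-4-1. The total count over the listed tRNAs lay between 12466839 and 12798174 in 13 of the 14 libraries and was 1866933 in the R-TCT-4 library of replicate 2. The most abundant tRNA, His-GTG-1-1, took 7.01% to 9.29% of each library's counts. Normalised signal tables covered the other 6 groups, RESTART v3 and the control treatment gctrl for each of the stop codons TAA, TAG and TGA. RESTART v3 pairs guide-directed pseudouridylation of a premature stop codon with a near-cognate tRNA, a tRNA whose anticodon reads a codon 1 base away from the stop codon. The signal tables held 235 isodecoders (tRNAs sharing an anticodon but differing in sequence) and 47 isoacceptors (1 value per anticodon), with column totals from 732359 to 1121706. Read depth behind the signal values is unknown. The columns carry codes in place of treatment names, and no label states that the code 3 stands for RESTART v3 and the code 1 for gctrl, so every direction in the signal tables rests on that reading. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples.

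The first question was how far each overexpressed tRNA rose above its level in untreated cells. All 6 were higher in both of their own libraries than in each of the other 12 libraries. Arg-TCT-4-1, which was scarce in untreated cells, rose 32.4-fold, and Arg-TCG-4-1 rose 3.02-fold. Arg-TCT-1-1, Trp-CCA-2-1, Trp-CCA-4-1 and Arg-TCG-1-1 were estimated 1.75-fold to 2.14-fold higher, and these differences did not pass edgeR's main test. Arg-TCT-4-1 (gene TRR-TCT4-1, GRCh38 chromosome 1, 159141611 to 159141684, inside an intron of AIM2) reached 1187 ± 153 counts per 1000000 listed tRNA counts (CPM; SD, n = 2) against 38.6 ± 2.25 in untreated cells. Its log2 fold change was 5.02 (SE 0.29) with an adjusted p of 3.85e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 252 tRNAs. Arg-TCG-4-1 (TRR-TCG4-1, chromosome 6, 26299677 to 26299749, no annotated gene overlapping) reached 1813 ± 152 CPM against 600.4 ± 198, a log2 fold change of 1.59 (SE 0.27) with an adjusted p of 0.00617. Without the untreated library of replicate 2 that value was 1.26 with an adjusted p of 0.0889.

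The other 4 overexpressed tRNAs had positive fold changes in edgeR's test that were not called at an adjusted p under 0.05. Arg-TCT-1-1 (TRR-TCT1-1, chromosome 1, 93847573 to 93847657, overlapping an exon of AL049796.1) reached 18305 ± 8137 CPM against 8986 ± 651. DESeq2 called it, with a log2 fold change of 1.02 and an adjusted p of 0.0191. EdgeR also called it against untreated cells joined by the groups of other anticodons (1.198, adjusted p 0.00323). In edgeR's main test its log2 fold change was 1.03 (SE 0.25) with an adjusted p of 0.159, and that value rested on 1 library. It was 1.47 with an adjusted p of 1.01e-05 without the R-TCT-1 library of replicate 1, when 101 tRNAs were called in this comparison, and 0.51 with an adjusted p of 0.388 without that of replicate 2. Arg-TCG-1-1 (TRR-TCG1-1, chromosome 15, 89335073 to 89335145, overlapping an exon of AC124068.2) stood at 8495 ± 179 CPM against 5011 ± 669, a log2 fold change of 0.81 (SE 0.24) with an adjusted p of 0.556. Trp-CCA-2-1 (TRW-CCA2-1, chromosome 17, 19508181 to 19508252, inside an intron of SLC47A1) stood at 1254 ± 15.6 CPM against 612.8 ± 135. Trp-CCA-4-1 (TRW-CCA4-1, chromosome 12, 98504252 to 98504323, no annotated gene overlapping) stood at 816.8 ± 38.0 CPM against 391.9 ± 31.1. Their log2 fold changes were 1.10 (SE 0.44) and 1.10 (SE 0.40), with adjusted p of 0.996 and 0.999. Leaving the R-TCT-1 library of replicate 2 out of the common fit left these values at 0.81 for Arg-TCG-1-1 and 1.10 for both Trp-CCA tRNAs but brought their adjusted p to 0.0365, 0.0282 and 0.0143, as the fitted biological coefficient of variation fell from 22.0% to 14.97%. That setting was chosen after the library had been seen to stand apart.

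**Figure D1:**
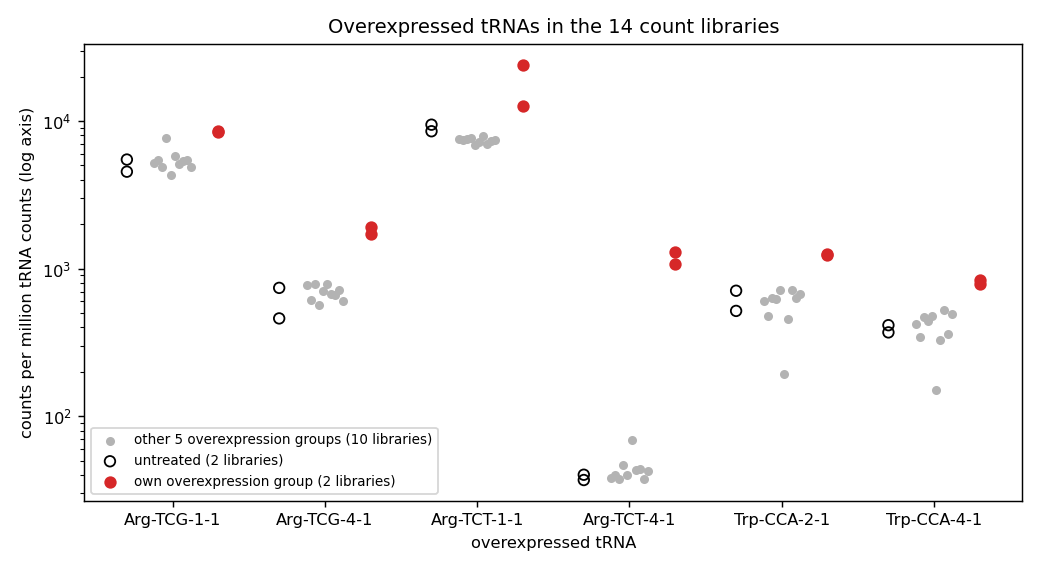
CPM (log axis) of the 6 overexpressed tRNAs in the 14 count libraries, with each point 1 library. Filled red points are the 2 libraries of the tRNA's own overexpression group, open circles the 2 untreated libraries and grey points the 10 libraries of the other 5 overexpression groups. The lowest red point lies above every other library by 1.08-fold for Arg-TCG-1-1 to 15.6-fold for Arg-TCT-4-1.

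Shares of whole anticodons were compared without a test. The Arg-TCG anticodon took 1.73% ± 0.101 (SD, n = 2) of tRNA counts with Arg-TCG-1-1 overexpressed and 1.56% ± 0.0134 with Arg-TCG-4-1 overexpressed, against 1.29% ± 0.270 in untreated cells. Arg-TCT took 2.21% ± 0.944 with Arg-TCT-1-1 and 1.10% ± 0.0356 with Arg-TCT-4-1 overexpressed, against 1.196% ± 0.0525. Trp-CCA took 0.255% ± 0.0135 and 0.254% ± 0.0118 with Trp-CCA-2-1 and Trp-CCA-4-1 overexpressed, against 0.187% ± 0.0247. In the overexpression groups of other anticodons Arg-TCG took 1.33% to 1.45%, Arg-TCT 0.990% to 1.03% and Trp-CCA 0.147% to 0.191%. The Arg-TCT share with Arg-TCT-4-1 overexpressed was thus below that of untreated cells but above that of those groups. Of the isodecoders that share an anticodon with the overexpressed tRNA, none was called in edgeR's test. The furthest from 0 were Arg-TCG-6-1 with Arg-TCG-1-1 overexpressed (log2 fold change 0.76, adjusted p 0.987) and Trp-CCA-3-1 with Trp-CCA-4-1 overexpressed (0.60, adjusted p 0.999). With Arg-TCT-1-1 overexpressed and its library of replicate 1 left out, all 4 other Arg-TCT isodecoders had log2 fold changes of 0.71 to 0.89. That leaves only the library of replicate 2. Its log2 deviations from the other 13 libraries were 0.72 for Arg-TCT-2-1, 0.76 for Arg-TCT-3-1 and 0.78 for Arg-TCT-5-1. For Arg-TCT-4-1 it was -0.04, where those 13 include the R-TCT-4 libraries. The labels do not say how reads that fit several near-identical tRNAs were counted, so values of single isodecoders are uncertain to that extent.

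The second question was how far the rest of the tRNA pool moved. In edgeR's main test Gln-TTG-4-1 was the only tRNA other than an overexpressed one that was called in any of the 6 comparisons. It was lower than in untreated cells in all 6. Group means of the tRNAs other than the target correlated closely with untreated cells. Gln-TTG-4-1 (TRQ-TTG4-1, chromosome 6, 145182723 to 145182794) had 951.4 and 1495 CPM in the untreated libraries and 18.7 to 25.0 CPM in the 12 overexpression libraries. Its log2 fold changes ran from -5.86 to -5.63, with adjusted p from 1.40e-08 to 2.01e-08 in edgeR's test. In the R-TCG-4 and R-TCT-4 comparisons 1 tRNA was higher, the overexpressed one, and 1 was lower. In each of the other 4 comparisons 0 were higher and 1 was lower. Between 3 and 11 tRNAs per comparison had an unadjusted p under 0.05. DESeq2 called 1 higher tRNA in the R-TCG-4, R-TCT-1 and R-TCT-4 comparisons and 0 in the others, with 1 or 2 lower in each. The further lower tRNA was Leu-TAA-4-1, in R-TCG-4, R-TCT-4 and W-CCA-4. Limma on log2(RPM + 1) also called it lower in R-TCT-4. Across tRNAs, which are not independent replicates, Pearson's r between group means of log2 CPM was 0.989 to 0.993 and Spearman's rho 0.987 to 0.994. The SD of the log2 fold changes of tRNAs other than the target was 0.47 to 0.53. With Gln-TTG-4-1 also left out, a setting chosen after its values were seen, it was 0.30 to 0.39, where the differences between replicates alone would give 0.30 to 0.55. The SD of the log2 difference between replicates was 0.56 in untreated cells and 0.23 to 0.93 in the overexpression groups. The R-TCT-1 group was the widest, with a replicate correlation of 0.959 against 0.988 to 0.998 in the other 6 groups.

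**Figure D2:**
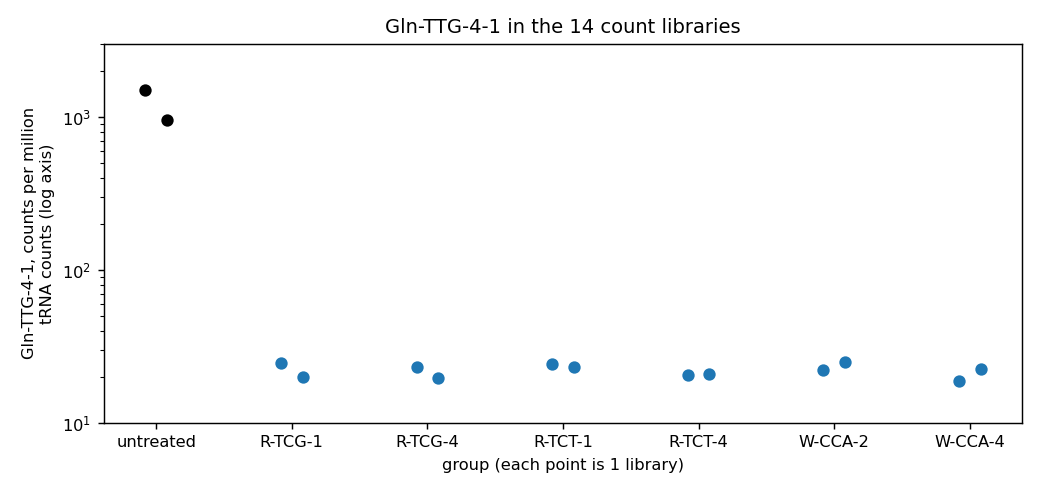
Gln-TTG-4-1 in CPM (log axis) in the 14 count libraries, with 1 point per library and 2 libraries per group. The untreated libraries lie at 951.4 and 1495, the 12 overexpression libraries between 18.7 and 25.0.

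Because the 6 comparisons share the same 2 untreated libraries, their chance values are shared. In 100 simulated data sets with unchanged groups, 0 had a tRNA called in all 6 comparisons, while the data had 1. Independent lists of the observed sizes would share at most 0.0159 tRNAs on average. With the overexpressed tRNAs left out, the mean pairwise correlation of log2 fold changes was 0.832 against a simulated 0.489, and the mean covariance was 0.207 against 0.0580. Gln-TTG-4-1 carried most of this. Without it, a setting chosen after its values were seen, the correlation was 0.653 against 0.489 and the covariance 0.0737 against 0.0581. The 2 untreated libraries were too few to be split into groups of 2. The simulation gave each tRNA the same dispersion in all libraries. The SD of the log2 difference between replicates was 0.56 in untreated cells and 0.23 to 0.54 in the overexpression groups other than R-TCT-1. The simulated spread of the shared untreated libraries may thus be too low. Part or all of the excess that remains without Gln-TTG-4-1 may come from them.

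No list of tRNAs passed a test of shift in one direction in the overexpression libraries. The lists were the near-cognate tRNAs of UAA, UAG and UGA, the other isodecoders of the target's anticodon, the other anticodons of its amino acid and all other tRNAs. Of 34 list tests with camera at a preset correlation of 0.01, 0 passed, with adjusted p from 0.110 to 0.987, while 9 had an unadjusted p under 0.05. With an estimated correlation 0 passed (adjusted p 0.905 to 0.991, 0 under 0.05 unadjusted), and fry also gave 0 (adjusted p 0.991, 0 under 0.05 unadjusted). Fry's mixed p-value, left unadjusted, was 3.41e-13 to 9.03e-11 for the UAA list, which holds Gln-TTG-4-1, in the 6 groups. With Arg-TCT-4-1 overexpressed it was 7.77e-06 for the UGA list, which holds the overexpressed tRNA, and 0.0407 for the other anticodons of arginine. The remaining mixed p-values were above 0.05. For the UAA list the mean and the camera direction differed in sign in 5 of the 6 groups, and Gln-TTG-4-1 is a member of that list. With Arg-TCT-4-1 overexpressed the camera direction was up for the UGA list at a median of -0.12 and a mean of -0.02, and up for the UAG list at a mean of -0.02. Mitochondrial tRNAs were not listed in the files.

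For TAA, the question was which tRNAs differed between RESTART v3 and gctrl. The glutamine tRNA Gln-TTG-1 was 8.05-fold higher with RESTART v3. Gln-TTG-3 rose 3.54-fold, while Gln-TTG-2 stood lower (log2 fold change -0.77) and was not called, and the Gln-TTG isoacceptor did not pass the main test. The other near-cognate anticodons of UAA had estimated log2 fold changes close to 0, most with wide intervals, and were not called. Gln-TTG-1 had a signal of 33081 ± 4665 (SD, n = 2) against 4145 ± 982, a log2 fold change of 3.01 (SE 0.47) with an adjusted p of 1.11e-07 by limma with Benjamini-Hochberg adjustment over 224 isodecoders. Gln-TTG-3 had 17536 ± 5845 against 4950 ± 1643, a log2 fold change of 1.82 (SE 0.48) with an adjusted p of 0.0175. That second call was lost on leaving out any of the 4 libraries, with fold changes from 1.48 to 2.17, the lowest without the RESTART v3 library of replicate 2 (adjusted p 0.994), and with a replicate block (1.82, adjusted p 0.156). In limma 2 isodecoders were higher and 0 lower, and 3 had an unadjusted p under 0.05. Among 47 isoacceptors 0 passed and 1 had an unadjusted p under 0.05. This was Gln-TTG, at 65887 ± 24471 against 8532 ± 842, a log2 fold change of 2.90 (SE 0.35). Its limma adjusted p was 0.101 over all isoacceptors and 0.0129 adjusted over the list alone of 6 near-cognate anticodons. It was called with median centring (2.73, adjusted p 0.00148), quantile normalization (2.86, 0.00205) and all 12 libraries in one fit (2.90, 0.000786). Without the RESTART v3 library of replicate 1 its log2 fold change was 3.29. The other 5 near-cognate isoacceptors, Glu-TTC, Lys-TTT, Ser-TGA, Leu-TAA and Tyr-GTA, had log2 fold changes from -0.22 to 0.09 (SE 0.21 to 0.55). Except for Lys-TTT (-0.72 to 0.55), their confidence intervals reached beyond 2-fold both ways, so such changes are not excluded. Features with non-overlapping groups numbered 12 of 47 isoacceptors (25.5%) and 31 of 224 isodecoders (13.8%), where chance gives 33.3%. The furthest of these that did not pass were Ile-AAT (0.61), Lys-CTT (0.51), Arg-TCG (-0.14), Leu-CAA (-0.10) and Ser-GCT (-0.09) among isoacceptors. Among isodecoders they were Glu-CTC-2 (0.40), Gln-TTG-2 (-0.77), Gln-CTG-4 (-0.63) and Gln-CTG-5 (-0.62).

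In the TAG tables the tRNA that rose was Gln-CTG-1, which was 2.97-fold higher with RESTART v3. Most other isodecoders lay slightly lower with RESTART v3 than with gctrl, with a median log2 fold change of -0.35. Below that shift lay Gln-CTG-4 and Gln-CTG-3, minor isodecoders of the same anticodon. Over TAA and TGA, where Gln-CTG-1 was not called, Gln-CTG-4 also averaged -0.42 relative to the median, and Gln-CTG-3 averaged -0.05. The test of a difference between stop codons called neither, so these falls are not shown to be particular to TAG. Gln-CTG-1 had a signal of 69328 ± 10825 (SD, n = 2) against 23342 ± 3842, a log2 fold change of 1.57 (SE 0.25) with a limma adjusted p of 1.32e-07. Centred on the median isodecoder of each library its log2 fold change was 1.92. Gln-CTG-4 fell from 1114 ± 235 to 496.9 ± 58.4, a log2 fold change of -1.15 (SE 0.24, limma adjusted p 0.000383), or -0.80 relative to the median. Gln-CTG-3 fell from 2574 ± 281 to 1345 ± 35.0, a log2 fold change of -0.93 (SE 0.25, limma adjusted p 0.0124), or -0.58 relative to the median. With centring Gln-CTG-4 passed (adjusted p 0.0273) and Gln-CTG-3 did not (adjusted p 0.592). Under quantile normalization neither did, at -0.71 and -0.60. Without the RESTART v3 library of replicate 1 neither passed (adjusted p 0.0824 and 0.177), and Gln-CTG-3 also did not without that of replicate 2 (0.294). Of 224 isodecoders 1 was higher and 2 lower. The number was 30 without the gctrl library of replicate 2, and 1 without the RESTART v3 library of replicate 1. Before adjustment 50 had a p under 0.05, of which 49 were lower. Among isoacceptors 14 had an unadjusted p under 0.05, and Gln-CTG was the 1 called, at 80158 ± 21280 against 38076 ± 1532, with a log2 fold change of 1.05 (SE 0.23, limma adjusted p 0.0088). Without the RESTART v3 library of replicate 2 it was 0.77 with an adjusted p of 0.260. A replicate block left the log2 fold changes of Gln-CTG-1 (1.57) and the Gln-CTG isoacceptor (1.05) as they were but brought their adjusted p to 0.0959 and 0.0519. With that block Gln-CTG-4 and Gln-CTG-3 did not pass either (limma adjusted p 0.234 and 0.643), nor with the crossed block (0.113 for both), at unchanged folds. The count of called isoacceptors rose to 2 without the gctrl library of replicate 1 and to 7 without that of replicate 2. The other near-cognate isoacceptors, Lys-CTT, Ser-CGA, Leu-CAA, Trp-CCA and Tyr-GTA, had log2 fold changes from -0.46 to -0.02, against a median of -0.30. Limma with a replicate block called Lys-CTT lower (adjusted p 0.0325), and Tyr-GTA stood at -0.72 without the gctrl library of replicate 2. Isoacceptors furthest down without passing were iMet-CAT (-0.73), Leu-AAG (-0.65) and Lys-TTT (-0.64), and among isodecoders Cys-GCA-9 (-0.76). Whether they passed depended on the setting. With a replicate block the 3 isoacceptors passed (each at an adjusted p of 0.0324) among 12 called, all lower. Without the gctrl library of replicate 2 they passed at 0.0262, 0.0262 and 0.0452, and Cys-GCA-9 at 0.00906. With the other trend setting Lys-TTT (0.00566) and Cys-GCA-9 (0.0167) passed. Non-overlapping groups were found for 28 of 47 isoacceptors (59.6%) and 151 of 224 isodecoders (67.4%), where chance gives 33.3%. Both RESTART v3 columns of the isodecoder table had lower totals (874044 and 856348) than both gctrl columns (1081968 and 972354). With centring, counted after this was seen, groups did not overlap for 15 isoacceptors (31.9%) and 66 isodecoders (29.5%), and 3 isodecoders had an unadjusted p under 0.05, 1 higher and 2 lower. A Glu-CTC isoacceptor value was not in the tables and was not analysed here.

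In the TGA tables the arginine tRNA Arg-TCT-1 rose 7.96-fold with RESTART v3. Arg-TCT-5, a scarce isodecoder of the same anticodon, rose 2.38-fold. No tRNA was called lower, and the median isodecoder was at a log2 fold change of -0.19. Arg-TCT-1 had a signal of 67250 ± 2551 (SD, n = 2) against 8645 ± 2586, a log2 fold change of 2.99 (SE 0.34) with a limma adjusted p of 6.99e-15. Centred on the median isodecoder of each library it was 3.12. Arg-TCT-5 had 40.1 ± 10.6 against 17.01 ± 8.60, a log2 fold change of 1.25 (SE 0.25, limma adjusted p 7.66e-05). That call was lost without the gctrl library of replicate 1 (0.74, adjusted p 0.116) and without the RESTART v3 library of replicate 1 (0.99, adjusted p 0.892) or of replicate 2 (1.52, adjusted p 0.599). With a replicate block the log2 fold changes of Arg-TCT-1 (2.99) and Arg-TCT-5 (1.25) were unchanged, with adjusted p of 0.0523 and 0.851. Of 222 isodecoders 2 were higher and 0 lower, and 7 had an unadjusted p under 0.05. With the gctrl library of replicate 1 left out 5 were called, 1 higher and 4 lower. Under quantile normalization Arg-TCT-1 had a log2 fold change of 2.98 with an adjusted p of 0.0513, and the 2 isodecoders called there, Asp-GTC-2 and Gly-GCC-1, were lower. The Arg-TCT isoacceptor stood at 69465 ± 3189 against 11020 ± 2724, a log2 fold change of 2.68 (SE 0.22, limma adjusted p 2.58e-06), and was the 1 isoacceptor called. The other 6 near-cognate isoacceptors, Arg-TCG, Gly-TCC, Ser-TGA, Leu-TAA, Cys-GCA and Trp-CCA, lay between -0.33 and 0.17. Under quantile normalization limma called 9 isoacceptors. Among them were Ser-TGA, higher (0.29, adjusted p 0.0142), and Val-AAC (-0.40, 0.00879) and iMet-CAT (-0.33, 0.0118), lower. Among features with non-overlapping groups that did not pass the main test, the lowest were Pro-TGG (-0.48), Val-AAC (-0.46) and iMet-CAT (-0.46) among isoacceptors. Among isodecoders they were Arg-TCT-4 (-0.59), Arg-TCT-2 (-0.51) and Glu-TTC-3 (-0.50). Groups did not overlap for 17 of 47 isoacceptors (36.2%) and 91 of 222 isodecoders (41.0%), where chance gives 33.3%, and with centring for 15 (31.9%) and 55 (24.8%). The selenocysteine isoacceptor SeC-TCA, which decodes UGA, had log2 fold changes of -0.08, 0.02 and -0.01 in the TAA, TAG and TGA tables and did not pass the test in any of them. Its 1 isodecoder, SeC-TCA-1, had -0.35, -0.42 and -0.20, was not called either, and had non-overlapping groups in the TAA and TAG tables.

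**Figure D3:**
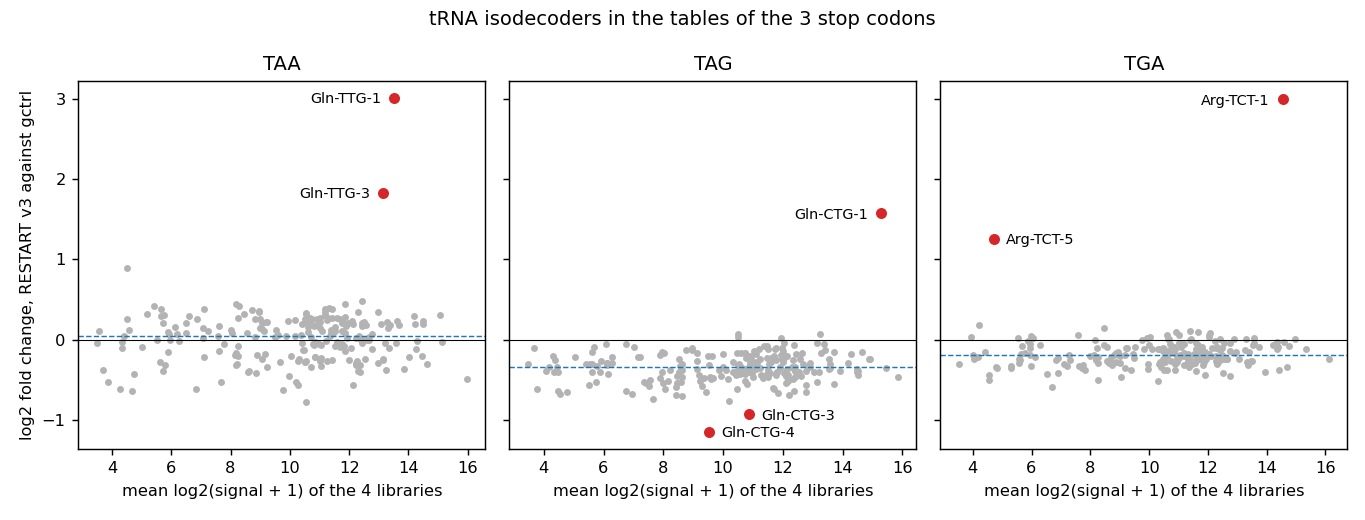
Log2 fold change of RESTART v3 against gctrl for each isodecoder, against its mean log2(signal + 1) over the 4 libraries of its stop codon, in 1 panel each for TAA, TAG and TGA. Red points were called by limma at an adjusted p under 0.05, grey points were not, and the dashed line marks the median isodecoder. Gln-TTG-1 (3.01), Gln-CTG-1 (1.57) and Arg-TCT-1 (2.99) stand above the other isodecoders of their panels.

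A further comparison asked whether any tRNA changed with RESTART v3 on average over the 3 stop codons. No tRNA passed in the planned fit over the 12 libraries. Limma called 0 of 47 isoacceptors and 0 of 224 isodecoders, with 9 and 31 at an unadjusted p under 0.05, of which 9 and 30 were lower. Most features lay slightly lower with RESTART v3. The median log2 fold change was -0.0940 for isoacceptors and -0.1475 for isodecoders, and 12.77% and 9.821% of them lay above 0. The fold changes of single tRNAs in this fit, Leu-TAA-2 and SeC-TCA included, are not relative to these medians. They therefore do not separate a fall of single tRNAs from this general shift. Centring and quantile normalization each called 5 isodecoders, Gln-TTG-1, Gln-TTG-3, Gln-CTG-1 and Arg-TCT-1 higher and Gln-CTG-4 lower. Such an average need not mean a like change. Within single stop codons Gln-TTG-1 and Gln-TTG-3 were called higher with TAA only, Gln-CTG-1 with TAG only and Arg-TCT-1 with TGA only. With the contrast averaged over 6 groups, a setting added after the data were seen, 4 were called, 2 higher and 2 lower. With a mean of at least 100 only Gln-CTG-4 was called, lower. Leaving out the RESTART v3 TAA library of replicate 2 gave 44 called isodecoders, and 3 were called without the gctrl TAA library of replicate 2. With the RESTART v3 TAA library of replicate 1 left out 2 were called, and 1 was called without the gctrl TGA or the RESTART v3 TGA library of replicate 1. For isoacceptors 7 were called without the gctrl TAA library of replicate 1. Among isodecoders 2 had non-overlapping groups (0.893%, where chance gives 0.216%). Leu-TAA-2, the 1 of these with a mean signal of at least 100, had a log2 fold change of -0.55 (SE 0.16, adjusted p 0.104). SeC-TCA had a log2 fold change of -0.02 as an isoacceptor and -0.32 as an isodecoder (adjusted p 0.955 and 0.350).

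The effect of RESTART v3 differed between stop codons for the tRNAs that had risen. RESTART v3 uses a near-cognate tRNA, which the labels do not name for any stop codon. As tRNA and stop codon change together, their effects are not separable here. Among the 3 tables, Gln-TTG-1 and Gln-TTG-3 were called higher with TAA only, Arg-TCT-1 and Arg-TCT-5 with TGA only, and Gln-CTG-1 with TAG only. Limma's test of the interaction of treatment and stop codon called 5 of 224 isodecoders, Gln-TTG-1 (adjusted p 1.00e-15), Arg-TCT-1 (6.48e-12), Gln-TTG-3 (4.70e-05), Arg-TCT-5 (0.000595) and Gln-CTG-1 (0.00927). It called 2 of 47 isoacceptors, Gln-TTG (0.00431) and Arg-TCT (0.0116), while the Gln-CTG isoacceptor had an adjusted p of 0.245. The log2 fold change of Gln-TTG-1 was larger in TAA than in TAG by 3.63 and than in TGA by 3.33. That of Arg-TCT-1 was lower in TAA than in TGA by a log2 difference of -2.80 and lower in TAG than in TGA by -3.29. For Gln-CTG-1 the difference was -1.59 for TAA minus TAG and 1.69 for TAG minus TGA. The Arg-TCT isoacceptor did not pass without the gctrl TGA library of replicate 1 (adjusted p 0.0787) or the RESTART v3 TGA library of replicate 1 (0.0661) or 2 (0.0794). Gln-CTG-1 did not pass on leaving out any of 5 libraries, with an adjusted p of up to 0.579 without the RESTART v3 TAG library of replicate 1. Arg-TCT-5 did not on leaving out any of 4, up to 0.505 without the gctrl TGA library of replicate 1. With a replicate block Gln-CTG-1 (0.0750), the Gln-TTG isoacceptor (0.103) and the Arg-TCT isoacceptor (0.188) did not pass. Without the RESTART v3 TAA library of replicate 1 the number of isodecoders called was 26, and it was 3 without either RESTART v3 TAG library or without the RESTART v3 TGA library of replicate 1.

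No near-cognate list passed a test of shift with RESTART v3. In 9 tests, 3 lists in each of 3 isodecoder tables, camera at a preset correlation of 0.01 called 0 with adjusted p from 0.219 to 0.637 and 1 at an unadjusted p under 0.05. An estimated correlation gave 0 (adjusted p 0.896, 0 unadjusted), and fry gave 0 (adjusted p 0.122 to 0.994, 2 unadjusted). Fry's test for change in either direction passed for the UGA list in the TGA table (adjusted p 0.00231), the list that holds Arg-TCT. In that table the list's camera direction was up, while its median and mean log2 fold changes were -0.26 and -0.13, against a table median of -0.19. The UAG list in the TAA table had a camera direction of down at a median of 0.05. Adjusted over the list alone, 2 isodecoders of the UAA list passed in the TAA table, 7 of the UAG list and 9 of the UGA list in the TAG table, and 2 of the UGA list in the TGA table. For TAG, 1 of the 33 members of the UAG list and 0 of the 46 of the UGA list had a fold above 1, both lists at a median of -0.38 against a table median of -0.35.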

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

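The interaction tests in this part were planned, while the comparison of counts outside the listed tRNAs was chosen after the result was seen.

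The R-TCT-4 library of replicate 2 has a signal outside the main measurement. Of the total that the authors divided by, 29.1% lay outside the listed tRNAs, against 1.51% and 3.37% in the untreated libraries and 0.781% to 3.37% in the other 13 libraries. What these reads are was not analysed here. The same library has the lowest total over listed tRNAs, 1866933 counts. Explanations for the outside share were not tested. Arg-TCT-4-1 was called with this library in and with it left out.

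The effect of RESTART v3 differed between the stop codons by limma's interaction test for 2 of 47 isoacceptors and 5 of 224 isodecoders. Gln-TTG had log2 fold changes of 2.90 with TAA, -0.60 with TAG and -0.24 with TGA (adjusted p 0.00431), and Arg-TCT had -0.05, -0.26 and 2.68 (adjusted p 0.0116). With a replicate block neither passed (adjusted p 0.103 and 0.188), and Arg-TCT did not without the gctrl TGA library of replicate 1 (0.0787) or the RESTART v3 TGA library of replicate 1 (0.0661) or 2 (0.0794). The called isodecoders were Gln-TTG-1 with 3.01, -0.62 and -0.32 (1.00e-15), Arg-TCT-1 with 0.19, -0.29 and 2.99 (6.48e-12), Gln-TTG-3 with 1.82, -0.40 and -0.10 (4.70e-05), Arg-TCT-5 with -0.53, -0.34 and 1.25 (0.000595) and Gln-CTG-1 with -0.02, 1.57 and -0.12 (0.00927). Each tRNA that rose is near-cognate to the stop codon of its own table. The labels do not name the tRNA used with each stop codon, and tRNA and stop codon change together, so their effects are not separable here. Gln-CTG-1 did not pass without the gctrl TAG library of replicate 1 (adjusted p 0.280), the RESTART v3 TAG library of replicate 1 (0.579) or 2 (0.143), or the RESTART v3 TGA library of replicate 1 (0.0722) or 2 (0.0548), nor with a replicate block (0.0750). Arg-TCT-5 did not pass without the RESTART v3 TAG library of replicate 1 (0.146) or 2 (0.128), the gctrl TGA library of replicate 1 (0.505) or the RESTART v3 TGA library of replicate 1 (0.193).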

How the results depend on the processing

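Every alternative chosen before the data were seen was run, and 10 were added after seeing the data, among them leaving the R-TCT-1 library of replicate 2 out of every contrast, chosen because it stood apart. Over 158 results, 1963 alternative values were computed, 1739 planned and 224 added. Of these 1816 kept direction and side of the threshold, a number that includes 71 sign changes with no call on either side. Calls were lost in 50 and gained in 33, 61 counts changed by over 1.5 times, and 3 values reversed. All 68 and 36 values of the list tests stayed on their side. Unless construction is named below, the cause was not tested. A lone library left in a group was assumed to vary like the others.

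Among the overexpressed tRNAs the log2 fold changes of all 6 stayed positive. Arg-TCT-4-1 was called under every alternative. Arg-TCG-4-1 was not called with only the 2 groups compared (1.60, adjusted p 0.0818), which leaves fewer libraries for the spread, and ran from 1.26 without the untreated library of replicate 2 (adjusted p 0.0889) to 2.05. Arg-TCT-1-1 was called against untreated cells with the groups of other anticodons (1.198, adjusted p 0.00323), against the 5 other overexpression groups (1.25, 0.00196) and by DESeq2 (1.02, 0.0191). Leaving out 1 library it ran from 0.51 (0.388) to 1.47 (1.01e-05), without R-TCT-1 replicates 2 and 1. Without the R-TCT-1 library of replicate 2 in any contrast, Arg-TCG-1-1 (0.81, 0.0365), Trp-CCA-2-1 (1.10, 0.0282) and Trp-CCA-4-1 (1.10, 0.0143) were called, and Leu-TAA-4-1, a tRNA singled out after its values were seen, was called lower in R-TCG-4 (-1.17, 0.0278), R-TCT-4 (-1.35, 0.00941), W-CCA-2 (-1.10, 0.0444) and W-CCA-4 (-1.34, 0.0125). It was also called lower by DESeq2 in R-TCG-4, R-TCT-4 and W-CCA-4, and in R-TCT-4 by limma on log2(RPM + 1) and with only the 2 groups.

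With the groups of other anticodons added to the reference the number of called tRNAs was 2 in R-TCG-1, 2 in R-TCT-1, 0 in W-CCA-2 and 2 in W-CCA-4. The call gained in R-TCG-1, R-TCG-4 and W-CCA-4 was Arg-TCT-4-1, lower by construction, as R-TCT-4 is in that reference. Without the R-TCT-1 library of replicate 2 in any contrast it was 2 in R-TCG-1, 3 in W-CCA-2 and 3 in W-CCA-4. It was 1 in R-TCG-4 with only the 2 groups compared, 2 in R-TCT-1 and 2 in W-CCA-4 by DESeq2, and 1 in R-TCT-4 and 0 in W-CCA-2 against the 5 other overexpression groups. Leaving out 1 library gave 1 to 3 in R-TCG-4 (1 without the untreated library of replicate 2) and 1 to 101 in R-TCT-1. Gln-TTG-4-1 reversed against the 5 other overexpression groups, which leaves out untreated cells, to 0.039 in R-TCG-1, 0.081 in R-TCT-1 and 0.16 in W-CCA-2, uncalled.

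In the TAA tables Gln-TTG-1 was called under every alternative, from 2.77 to 3.25. The Gln-TTG isoacceptor became the 1 call with median centring (2.73, adjusted p 0.00148), quantile normalization (2.86, 0.00205) and all 12 libraries in one fit (2.90, 0.000786). Leaving out 1 library gave 0 to 1 isoacceptors, with 1 without the RESTART v3 library of replicate 1, and 1 isodecoder each time. In the TAG tables Gln-CTG-1 was 1.40 to 1.92. Isoacceptors called were 0 with quantile normalization (Gln-CTG 1.03, 0.378), 0 with all 12 libraries (0.191), 4 with the other trend setting and 0 to 7 leaving out 1 library (0 without the RESTART v3 library of replicate 2, 7 without the gctrl library of replicate 2). Isodecoders were 22 with the other trend setting and 1 to 30 leaving out 1 library (30 without the gctrl library of replicate 2, 1 without the RESTART v3 library of replicate 1). Quantile normalization called 4, of which 1 was shared. Centring moved the median isodecoder from -0.35 by construction.

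In the TGA tables the Arg-TCT isoacceptor was called under every alternative, from 2.42 to 2.93, and quantile normalization called 9 isoacceptors. Isodecoders called were 1 with a mean of at least 100, a filter that removes Arg-TCT-5, and 1 to 5 leaving out 1 library (5 without the gctrl library of replicate 1, 1 without either RESTART v3 library). Quantile normalization called 2, both lower and 0 shared, with Arg-TCT-1 at 2.98 (0.0513). Over the 3 stop codons isodecoders called were 1 with a mean of at least 100, 5 with centring, 5 with quantile normalization, 4 with the contrast averaged over 6 groups and 0 to 44 leaving out 1 library (44 without the RESTART v3 TAA library of replicate 2). Isoacceptors were 0 to 7 (7 without the gctrl TAA library of replicate 1). The interaction called 1 to 2 isoacceptors and 3 to 26 isodecoders leaving out 1 library (26 without the RESTART v3 TAA library of replicate 1).

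The labels do not say that equal replicate numbers pair libraries. Correlations of deviations between groups ran from -0.522 to 0.518 over 21 pairs of count groups (9 over 0.1) and from -0.467 to 0.499 in the signal tables. With a replicate block no call of the overexpression comparisons changed, with the targets at 0.81, 1.63, 1.01, 5.02, 1.13 and 1.11. In the signal tables the block called 1 isodecoder in TAA, 12 isoacceptors (all lower) and 0 isodecoders in TAG, 0 isodecoders in TGA and 0 isoacceptors in the interaction, with folds unchanged, and it leaves 1 residual degree of freedom per table. Pairing replicates 1 and 2 instead called 1 isodecoder in TAA, 1 in TAG and 6 in TGA.

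Depth limited the R-TCT-4 library of replicate 2, where 3 counts are 1.61 CPM. The depth of the signal libraries is unknown.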

Other observations

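The tests of explanations in this part were chosen after the results were seen, except the comparison of the R-TCT-1 library of replicate 2 with the TGA table, which was written before.

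Gln-TTG-4-1 was high in the untreated libraries (951.4 and 1495 CPM) and low in all 12 overexpression libraries (18.7 to 25.0 CPM). A swap of libraries between groups is argued against, since in 12 of 12 overexpression libraries the overexpressed tRNA exceeded its level in every library of the other groups. Reads shared with other Gln-TTG isodecoders stay open. The summed mean level of those isodecoders was 1552 CPM higher in the overexpression libraries, while Gln-TTG-4-1 was 1201 CPM higher in untreated cells. The SD of that sum between the untreated libraries was 2748 CPM, and its lower untreated mean rests on replicate 2. All Gln-TTG tRNAs together took 1.178% of counts in untreated replicate 1 and 0.7348% in replicate 2. Their means in the overexpression groups were 0.8706% to 1.117%. Gln-CTG was low in untreated replicate 2 too (1.351%, against 2.252% in replicate 1). The mean difference therefore does not show a transfer of reads. A source outside the cells of the untreated libraries may also apply. Besides Gln-TTG-4-1, 1 other tRNA of 252, Leu-TAA-4-1, was higher in untreated cells than in the mean of the 6 overexpression groups (log2 fold change 1.123, edgeR adjusted p 0.0350), which does not decide it. In the gctrl libraries Gln-TTG-4 had a signal of 13.02 to 21.8. Their isodecoder columns totalled 834595 to 1087058, so the scale is near that of CPM, though the normalization is not fully described. On that scale the gctrl libraries lay near the overexpression libraries and far below the untreated ones. The untreated libraries may thus be the ones that stand apart. As gctrl is itself a treatment, measured in other tables, these values do not decide the cause. A response to overexpression as such stays open and untested, because all 6 groups share the same 2 untreated libraries.

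The R-TCT-1 library of replicate 2 stood apart from the other 13. The SD of its log2 deviation from the other libraries was 0.87 over 239 tRNAs, against 0.17 to 0.55 elsewhere, and 43 tRNAs were over 2-fold lower and 8 over 2-fold higher. Anticodon accounted for 70.3% of the variance of the deviation, with the lowest means for Leu-CAG (-1.79), Ile-TAT (-1.76) and Val-CAC (-1.56) and the highest for Cys-GCA (0.84) and Arg-TCT (0.75). The Arg-TCT mean includes the overexpressed Arg-TCT-1-1 itself (1.54). Lower depth of the deposited counts is argued against by a total 0.987 times the median of the other 13. The totals that the authors divided by were nearly equal, 12893174 to 12902889, in 13 libraries including this one. Why they were so close is not stated, so a total cannot show the depth before processing, and lower depth there stays open. A swap with another group is argued against by this library's Arg-TCT-1-1 level, 2.55 times that of the highest library of the other groups. For a response of other tRNAs to more Arg-TCT-1-1, r was -0.0555 between that library's deviations and the TGA fold changes. This was over 217 isodecoders, which are not independent replicates (-0.0964 for TAA and -0.0824 for TAG). The SD of the TGA fold changes of uncalled isodecoders was 0.137, against 0.234 and 0.240 for the log2 difference between replicates. With so little beyond replicate spread, and another treatment, a small r cannot decide, and this response stays open. A relation to tRNA length may be part of it: rho was -0.455 over 231 of the 239 tRNAs, between the sizes set as deciding for it (0.5) and against it (0.3), so this stays open. Other causes in library preparation were not tested.

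For the anticodons with 1 isodecoder, Ile-GAT and SeC-TCA, isoacceptor and isodecoder values should match but did not. The ratio of the tables ran from 0.621 to 1.61 for Ile-GAT and 0.774 to 1.29 for SeC-TCA. One scaling factor per library and table is argued against, because the ratio of the 2 anticodons' ratios varied 3.91-fold between libraries. Isodecoders missing from the isodecoder tables are argued against by ratios below 1, the lowest being 0.621. No biological explanation was tested.

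Isodecoders of the raised anticodon that were not called higher may fall when another rises. Gln-TTG-3 (1.82 with TAA) and Arg-TCT-5 (1.25 with TGA) share the raised anticodons, rose and were left out for that reason, so the values here are conditioned on not rising. Relative to the table's median, the 10 isodecoders left had a median log2 difference of -0.24 (SD 0.53) between their own table and the other tables, and 8 were below the median in their own table and 7 in the others. The spread leaves this open, and competition for reads was not separable from a change in level.

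Overexpressed tRNAs that are scarce in the cells may rise by a larger fold. Over the 6 targets, with the level taken from the 5 other overexpression groups and the fold against untreated cells, rho was -0.77 (exact p 0.103, Benjamini-Hochberg 0.103) and r was -0.81 (exact p 0.0292, Benjamini-Hochberg 0.0583) in 2 relations, by two-sided exact permutation tests. Without Arg-TCT-4-1 and Arg-TCT-1-1 r was -0.58 and rho -0.40, negative still, over too few tRNAs to decide. A fold is taken relative to the level in the cells, so equal gains in CPM would by themselves give a negative relation. The gains in CPM were 9318 for Arg-TCT-1-1, 3484 for Arg-TCG-1-1, 1212 for Arg-TCG-4-1, 1148 for Arg-TCT-4-1, 641 for Trp-CCA-2-1 and 425 for Trp-CCA-4-1. The relation therefore does not show that scarce tRNAs gained more.

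For RESTART v3 over the 3 stop codons limma called 0 isoacceptors and 0 isodecoders (9 and 31 at an unadjusted p under 0.05). In 100 splits of the 12 libraries into 6 and 6, all 100 gave at least as many at each level, which a real count of 0 makes certain, so the splits do not bear on chance. The highest other split called 6 isoacceptors and 78 isodecoders, and 2 and 14 of the splits called any. This may point to a structure of the samples, but what sets these splits was not tested.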
